A study of Mus musculus with 14 samples.

How the data were processed

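Bulk RNA-seq was run on pooled ventral spinal cord pieces of mice: 3 non-ablated lesion, 3 non-ablated distal, 4 ablated lesion and 4 ablated distal libraries. Per the labels' protocols, total RNA with a RIN given as above 0.68 was reverse-transcribed and amplified by multiple displacement amplification with a Qiagen single-cell RNA library kit, and sequenced on an Illumina NextSeq for 75 cycles. Whole-transcript amplification of this kind can add spread between libraries at low genes. The submitters' processing notes name bcl2fastq, BWA 0.7.17.1, DESeq2 and the mm10 build. The read counter, its use of strand and the gene annotation are not given in the sources used here.

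The deposited signal is a table of gene counts that the authors divided by a size factor per library with DESeq2 (normalized counts), per the labels. Dividing each column by its smallest step gave back whole reads for 100% of values within 0.01, and recovered totals of 23601763 to 30844575 reads per library. In distal_control 1 that step lies so near 1 that it cannot be separated from rounding. A gene at 0 allows up to 3 reads, for counting error only, and amplified reads without molecular identifiers are not independent molecules. The table holds 24116 genes, of which 4706 were at 0 in all libraries. The 8 entries without a gene symbol, 0.00265 to 0.0239% of reads, were left out of the named genes but kept in the tests where their counts sufficed. Entrez identifiers were matched to a RefSeq gene table of GRCm38.p6, with 24061 of 24116 matched, and coordinates are those of that table, 1-based.

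Groups were taken from the sample titles. The main test was limma 3.58.1 in R 4.3.3 (trend fitted) on log2(normalized count + 1), for 15637 genes with at least 10 normalized counts in at least 3 libraries. A single fit of 4 group means over all 14 libraries left 10 residual degrees of freedom, with 4.23 added by the prior. Each gene has 1 spread over the 4 groups, so distal standard errors and p-values do not measure distal spread alone. The 5 comparisons were lesion versus distal tissue within each genotype, ablated versus non-ablated within each region, and the interaction. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 within each comparison. Adjusted p-values of single genes in the text are limma's unless another tool is named.

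A total of 26 gene lists were fixed: homeostatic microglia, pan-macrophage, infiltrating monocyte, border macrophage, disease-associated phagocyte, neutrophil, T and NK cell, B cell, MHC class II, type I interferon response, chemokine and cytokine, complement, mature oligodendrocyte and myelin, oligodendrocyte progenitor, astrocyte, reactive astrocyte, neuron, endothelial and pericyte, fibroblast and extracellular matrix, Schwann cell, cell cycle, cholesterol biosynthesis, lipid efflux and storage, ependymal, blood cell and immediate early gene. Their 353 genes include 19 at 0 in all libraries and 4 not in the table. The 23 lists with at least 5 measured genes were tested with camera at a preset correlation of 0.01, two-sided, and adjusted over the 23 lists of a comparison. The groups, tests, gene lists, naming rule and most alternative settings were fixed before the data were examined.

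Genes were named by rule. In each comparison these were the 6 largest rises and 6 largest falls among called genes whose groups do not overlap, leaving out predicted genes, RIKEN clones, pseudogenes, mitochondrial genes and small RNAs by their symbols. Where a direction had fewer, those it had were named, and where it had none, the 3 with the smallest p were given as not passing. Further named genes were up to 4 members of each list with the smallest unadjusted p, and a fixed set: Tmem119, P2ry12, Sall1, Cx3cr1, Csf1r, Hbegf, Ccr2, Mbp and Gfap. Some genes that this rule takes are not reported here. Y-linked genes and Xist served only as a check of the sex makeup of the pools, in which Xist was listed at 0. Genes outside the rule are said to be chosen after their values were seen. To set the cell cycle list against genes of like level, each member was compared with the 50 genes outside the list nearest to it in mean log2 value over the distal libraries.

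Alternative settings fixed at that time were TMM, upper-quartile and quantile scaling, a pseudocount of 0.5 or 10, no filter or a filter at 50, array weights, a robust prior, only the groups compared, each replicate left out, edgeR 4.0.16 (quasi-likelihood) and DESeq2 1.42.0 on the recovered reads, and camera with an estimated correlation and fry for lists. A Y-linked score as covariate, the age label in months as a linear covariate with 1 slope over the groups, a replicate block by consecutive title numbers, and leaving out distal_control 5 with lesion_control 6 were added after seeing the data. On recovered reads edgeR called 4276, 4682, 47, 63 and 2 genes in the order non-ablated lesion response, ablated lesion response, ablation in lesions, ablation in distal tissue and interaction, of which limma also called 3999, 4323, 43, 48 and 2. DESeq2 called 5192, 5504, 259, 532 and 94, of which limma also called 4282, 4544, 45, 57 and 2, and gave no adjusted p for 296 genes.

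The tests were tested on simulated counts drawn from the real means and library sizes, with 100 genes changed 2-fold and 100 changed 4-fold. For the non-ablated lesion response (15481 genes), limma recovered 3% at 2-fold and 31% at 4-fold. For the ablated lesion response (15479 genes) it recovered 4% and 52%, for ablation in lesions (15487 genes) 2% and 38%, for ablation in distal tissue (15476 genes) 5% and 43%, and for the interaction (15495 genes) 0% and 7%. For ablation in lesions edgeR recovered 2% and 36% and DESeq2 8% and 58%. Unchanged genes made up 2.86%, 8.06%, 6.98%, 5.88% and 0% of limma's calls in the 5 simulations, and 9.52% of edgeR's and 34.3% of DESeq2's calls in that of ablation in lesions. A simulated list of 15 genes changed 2-fold passed camera in each comparison, and 0 of 22 unchanged lists did. Simulated genes were drawn independently, so these lists do not show how often camera calls unchanged lists of correlated genes. In the real data, other splits of the same libraries called up to 15 lists for ablation in lesions. Power for single genes at 2-fold was low, and a gene that was not called may still differ.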

Results

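RNA was measured in ventral spinal cord of mice in which a diphtheria toxin receptor could be switched on in Cx3cr1-expressing cells, a class that includes microglia, the resident macrophages of the central nervous system. Mice carried Cx3cr1-CreER, a tamoxifen-dependent recombinase, with the receptor allele (ablated) or without it (non-ablated). They received tamoxifen for 3 days, a focal injection of lysophosphatidylcholine (LPC), a detergent-like lipid that strips myelin, 4 to 6 weeks later, and daily diphtheria toxin until collection 5 days after LPC. Lesion tissue and distal uninjured tissue were microdissected, which gave 3 lesion and 3 distal libraries from non-ablated mice and 4 lesion and 4 distal libraries from ablated mice. Each library is given as a pool of 3 to 5 mice of both sexes, so the pool is the replicate. Y-linked scores ran from 3.33 in distal_ablated 13 to 8.32 in lesion_control 6, so the share of males may differ between pools. The design text counts 3 non-ablated and 4 ablated pools, so lesion and distal pieces of a genotype came from the same pools. The labels do not tie a lesion piece to its distal piece, and p-values between lesion and distal tissue ignore that pairing. Age labels rise by 1 month per library in the order of the titles, from 2 to 7 months over the non-ablated and from 8 to 15 over the ablated libraries. Pieces of 1 pool would share an age, yet each library has a different label, so the labels cannot all be true ages. The true ages are not given in the sources used here. Labelled ages do not overlap between the genotypes but vary within each group. Age was therefore entered as a linear term, with 1 slope over the groups, in an alternative fit chosen after seeing the data, which cannot separate a step in age between the genotypes from ablation. Libraries hold 23601763 to 30844575 recovered reads and 15949 to 17945 genes with at least 1 read. Over these, 15637 genes were tested with limma.

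Lesion and distal libraries separated on the leading principal component, which holds 45.9% of the variance. The next component holds 13.4% and is led by the library distal_ablated 9, which lies at 151.69 while the other 13 lie between -55.32 and 42.95. Pearson correlations of log2 values between libraries of a group were 0.864 to 0.938 in ablated distal tissue, 0.876 to 0.918 in non-ablated distal tissue, 0.925 to 0.966 in ablated lesions and 0.963 to 0.981 in non-ablated lesions. No pair of libraries of a group agreed within sampling noise, with a chi-square per degree of freedom of at least 31.5. Log2 fold changes below are on the log2(normalized count + 1) scale, which understates the change of low genes, and are given with their standard errors. Values of genes with close relatives, such as Mx1 and Mx2, which the RefSeq gene table lists as transcribed pseudogenes, and of overlapping or antisense genes are uncertain where reads could be split between them, since counting by strand is not stated. Lists were tested with camera at a preset correlation between genes, and calls that hold with an estimated correlation are named. A list call said to hold or to be lost otherwise is one made with that estimated correlation.

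Ablation was compared within lesions, the comparison that the series title names. Cx3cr1, the fractalkine receptor whose promoter drives the recombinase (Entrez 13051; GRCm38, the RefSeq assembly of mm10, chromosome 9, 120048683 to 120068296), checks the labels. Its normalized count was 4089 ± 556 (SD, n = 3) in non-ablated lesions and 236 ± 75.7 (SD, n = 4) in ablated lesions, a log2 fold change of -4.16 ± 0.51 (adjusted p = 0.00301). The non-ablated lesion libraries lay between 3657 and 4717 and the ablated ones between 155 and 336. Csf1r, the receptor on which microglia and macrophages depend (Entrez 12978; chromosome 18, 61105572 to 61131139), fell by 1.98 ± 0.38 on the log2 scale, from 11252 ± 2428 (SD, n = 3) to 2830 ± 389 (SD, n = 4; adjusted p = 0.0459). Mfge8, which encodes a bridging protein for the uptake of dying cells (Entrez 17304; chromosome 7, 79133768 to 79149060), rose by 1.61 ± 0.22, from 5412 ± 1351 (SD, n = 3) to 16323 ± 2060 (SD, n = 4; adjusted p = 0.00742).

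All 13 measured homeostatic microglia genes, markers of resting microglia, had negative log2 fold changes in ablated lesions, with a median of -2.15. Of these, 6 fell over all genes tested and 11 fell adjusted over the list alone. Siglech, a microglial lectin (Entrez 233274; chromosome 7, 55768154 to 55779448), fell by 5.25 ± 0.85, Fcrls by 2.73 ± 0.38 and Olfml3 by 2.09 ± 0.38. Tmem119, a microglial membrane protein, did not pass over all genes, at 28552 ± 4573 (SD, n = 3) in non-ablated and 5889 ± 4058 (SD, n = 4) in ablated lesions (adjusted p = 0.369). Nor did the microglial transcription factor Sall1 (-1.64 ± 0.37, adjusted p = 0.0901). P2ry12, a purinergic receptor marking microglia whose span lies within that of Med12l, is listed at 0 in all 14 libraries. The list passed camera (adjusted p = 3.4e-26; adjusted p = 0.000144 with an estimated correlation), and the exact two-sided permutation test of its mean score gave p = 0.0286, the smallest that 35 splits allow.

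The type I interferon response list, antiviral genes induced by interferon, was lower too. All 19 measured members had negative log2 fold changes, with a median of -2.78, and 4 fell over all genes while 16 fell adjusted over the list alone. Those past the threshold over all genes were Rtp4 (-3.21 ± 0.58), Mx2 (-2.87 ± 0.54), Xaf1 (-2.35 ± 0.43) and Trim30a (-1.87 ± 0.36). The call of this list rests on the preset correlation (camera adjusted p = 3.3e-26) and was lost otherwise (adjusted p = 0.104 with an estimated correlation), while the exact permutation p of its score was 0.0286. The libraries lesion_control 6 and distal_control 5 held the highest T and NK cell scores, 6.50 and 5.47 on the log2 scale against 0.86 to 4.14 in the other 12 libraries. Both are non-ablated libraries, and without lesion_control 6 the interferon median in lesions was -2.88.

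Of 16 measured pan-macrophage genes, 15 had negative log2 fold changes with a median of -0.47, and 1 fell over all genes (3 adjusted over the list alone): Fcgr1, a high-affinity antibody receptor, by 2.22 ± 0.38. Cd14, a co-receptor for bacterial lipopolysaccharide, had -1.28 ± 0.36 (adjusted p = 0.221). Of 17 disease-associated phagocyte genes, Cst7, a cysteine protease inhibitor, fell by 4.67 ± 0.57 as the sole member over all genes. Adjusted over the list alone, 4 fell and 1 rose. Its list median was -0.02 and its mean -0.40. The growth factor gene Igf1 (-1.44 ± 0.38, adjusted p = 0.188), Ch25h (-3.26 ± 0.84, adjusted p = 0.17) and the receptor kinase gene Axl (-1.05 ± 0.24, adjusted p = 0.0943) did not pass. Both lists passed camera as lower (adjusted p = 1.6e-05 and 0.0489), and both calls were lost otherwise (adjusted p = 0.26 and 0.472 with an estimated correlation). The phagocyte call was also lost without lesion_control 6, lesion_ablated 10 or lesion_ablated 12 (camera adjusted p = 0.126, 0.0923 and 0.183), and its median lay between -0.11 and 0.0088 over libraries left out and was -0.20 after quantile normalization.

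Other called genes of large change in ablated lesions were Capn3, a calcium-dependent protease (Entrez 12335; chromosome 2, 120463593 to 120504919), which fell by 5.66 ± 0.68, the inhibitory receptor gene Cd72 (-4.54 ± 0.73), Lrrc3 (-4.43 ± 0.67) and Dyrk4 (-4.34 ± 0.51). The 5 genes that rose were Spsb4 (1.79 ± 0.32), Mfge8, Papss2 (1.56 ± 0.26), the glutathione transferase gene Mgst1 (1.48 ± 0.25) and Epas1, a hypoxia-responsive transcription factor (1.23 ± 0.22).

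Markers of neural cells were higher in ablated lesions as lists, with no single gene past the threshold over all genes. All 16 mature oligodendrocyte and myelin genes were positive (median 0.57), as were all 12 astrocyte genes (median 0.63; 1 rose adjusted over the list alone) and all 16 neuron genes (median 0.80). Mbp, a major myelin protein gene, was at 129367 ± 30228 (SD, n = 3) and 188828 ± 20972 (SD, n = 4; adjusted p = 0.616), and Mog, Mobp, the astrocyte gene Mlc1 and the neuronal tubulin gene Tubb3 had 0.81 ± 0.25, 0.61 ± 0.21, 0.99 ± 0.28 and 0.99 ± 0.34. Gfap, the astrocyte intermediate filament, had 0.75 ± 0.24 (adjusted p = 0.311). The 3 lists passed camera (adjusted p = 1.2e-10, 5.9e-06 and 0.000816) and none passed otherwise (adjusted p = 0.212, 0.173 and 0.408 with an estimated correlation). The neuron call was lost without lesion_ablated 10 (median 0.49, camera adjusted p = 0.0665) and its median was 1.25 without lesion_ablated 8, 1.45 with edgeR and 1.43 with DESeq2, while without lesion_ablated 14 the astrocyte list passed otherwise too (adjusted p = 0.0147 with an estimated correlation). The oligodendrocyte progenitor, reactive astrocyte, endothelial and pericyte, and cholesterol biosynthesis lists were also called higher by camera (medians 0.36, 0.45, 0.38 and 0.27), and the chemokine and cytokine, complement and cell cycle lists lower (medians -0.34, -0.64 and -0.72). None of these 7 passed otherwise (adjusted p = 0.311, 0.315, 0.304, 0.311, 0.26, 0.408 and 0.108 with an estimated correlation). Camera calls were lost without lesion_control 2 for endothelial and pericyte genes (median 0.21, adjusted p = 0.125) and without lesion_control 6 for progenitor, cholesterol biosynthesis and complement genes (medians 0.27, 0.14 and -0.13; adjusted p = 0.0697, 0.155 and 0.379). Without lesion_ablated 14 they were lost for progenitor and complement genes (adjusted p = 0.0513 for each), and without lesion_ablated 10 or lesion_ablated 12 for complement genes (adjusted p = 0.0923 and 0.0596). The cholesterol biosynthesis median was 0.47 without lesion_control 2, the complement median -0.37 with array weights, and without lesion_control 6 the cell cycle list passed otherwise too (adjusted p = 0.0463 with an estimated correlation).

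Over all genes, limma called 46 of 15637 in this comparison, 5 higher and 41 lower, with 1128 at an unadjusted p under 0.05. Of 23 lists, 14 passed camera, 7 higher and 7 lower, 1 of them with an estimated correlation. The members Ccl12 (-4.26 ± 0.89, adjusted p = 0.0695), C1qa (-1.33 ± 0.29, adjusted p = 0.0819), Top2a (-1.14 ± 0.48, adjusted p = 0.588), Fn1 (-1.34 ± 0.38, adjusted p = 0.241), Ifi27l2a (-3.13 ± 0.75, adjusted p = 0.127) and the border macrophage gene F13a1 (1.99 ± 0.71, adjusted p = 0.435) did not pass. Ccr2, the chemokine receptor of recruited monocytes, was at 663 ± 446 (SD, n = 3) and 614 ± 217 (SD, n = 4), and the growth factor gene Hbegf at 1823 ± 453 (SD, n = 3) and 2416 ± 878 (SD, n = 4), both with adjusted p = 0.999. The infiltrating monocyte list, whose median (0.08) and mean (-0.28) differ in sign, was not called (adjusted p = 0.378). The B cell, MHC class II and blood cell lists had 3 measured genes each and were not tested as lists in any comparison. By limma 0 of their genes passed here. The border macrophage, neutrophil, T and NK cell, fibroblast and extracellular matrix, Schwann cell, lipid efflux and storage, ependymal and immediate early gene lists did not pass either (camera adjusted p = 0.124, 0.942, 0.0539, 0.121, 0.441, 0.496, 0.287 and 0.15). The gene count was 9 without lesion_control 6, 5 without lesion_control 2, 8 without lesion_control 4, 16 without lesion_ablated 8, 14 without lesion_ablated 10 and 11 without lesion_ablated 12. With 10.9% of the 46 higher by limma, it was 1013 with array weights (45.4% higher), 416 with these groups fitted alone (25% higher), 259 with DESeq2 (34.4% higher), 101 after quantile normalization, 98 with a pseudocount of 10, 47 with edgeR and 30 with a Y-linked score in the fit. With the age label as a linear term, standard errors were 1.61 times as large at the median and limma called 2 genes, Capn3 and Cst7, the sole named genes of the 20 called that passed under every setting tried. Cx3cr1 then had -4.85 ± 0.80 (adjusted p = 0.0947), Csf1r -2.28 ± 0.61, Mfge8 1.28 ± 0.34 (adjusted p = 0.249 for each) and Epas1 0.78 ± 0.32 (adjusted p = 0.513). The microglia list had a median of -2.99 and passed camera both ways (adjusted p = 1.4e-13; adjusted p = 0.00278 with an estimated correlation). In that fit camera did not call the reactive astrocyte, endothelial and pericyte, and cell cycle lists (medians 0.20, 0.23 and -0.699; adjusted p = 0.793, 0.3401 and 0.0910). It called the infiltrating monocyte, T and NK cell and fibroblast lists lower (adjusted p = 0.00118, 7.8e-05 and 0.00403). Medians were -1.28 for pan-macrophage, -0.46 for phagocyte, -1.15 for chemokine and cytokine, -0.97 for complement, 1.04 for myelin and 0.65 for cholesterol biosynthesis genes.

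**Figure D1:**
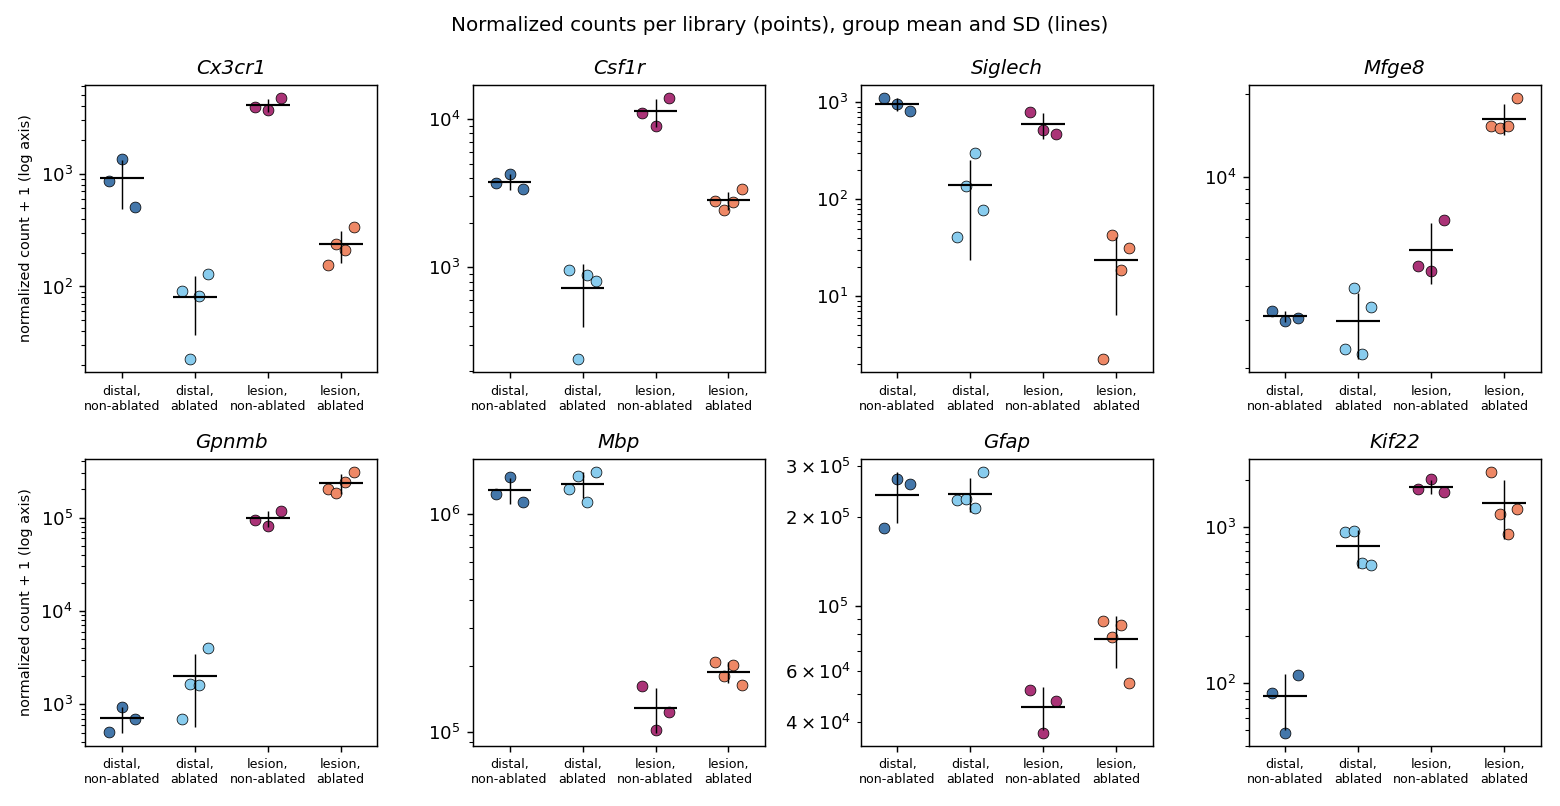
Normalized count plus 1 per library on a log axis for 8 genes in the 4 groups, with group means (horizontal lines) and SDs (vertical lines). Cx3cr1 lay between 3657 and 4717 in the 3 non-ablated lesion libraries and between 155 and 336 in the 4 ablated ones.

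In distal tissue the same comparison gives the effect of ablation away from the lesion. Cx3cr1 fell by 3.62 ± 0.51, from 911 ± 427 (SD, n = 3) to 80.2 ± 43.9 (SD, n = 4; adjusted p = 0.00922), and Csf1r by 2.55 ± 0.38, from 3769 ± 450 (SD, n = 3) to 724 ± 329 (SD, n = 4; adjusted p = 0.0122). Selplg, a selectin ligand of leukocytes, fell by 2.83 ± 0.33 and Csf3r, the granulocyte colony-stimulating factor receptor (Entrez 12986; chromosome 4, 126023441 to 126044975), by 3.52 ± 0.34, from 922 ± 184 (SD, n = 3) to 84.4 ± 36.4 (SD, n = 4; adjusted p = 0.000759). Kif22, a kinesin of the mitotic spindle (Entrez 110033; chromosome 7, 127027729 to 127042467), rose by 3.23 ± 0.35, from 81.7 ± 32.5 (SD, n = 3) to 752 ± 204 (SD, n = 4; adjusted p = 0.00154).

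All 13 homeostatic microglia genes were negative in ablated distal tissue, with a median of -1.86 (-1.19 with DESeq2), and 3 fell over all genes (7 adjusted over the list alone). The fructose transporter gene Slc2a5 had -2.98 ± 0.69 (adjusted p = 0.0936). All 16 pan-macrophage genes were negative with a median of -1.45, and 2 fell (10 adjusted over the list alone): Cd14 by 2.36 ± 0.36 and Fcgr1 by 2.23 ± 0.38. The lysosomal protease gene Ctss had -2.22 ± 0.45 (adjusted p = 0.0534). Camera called both lists lower (adjusted p = 1.1e-12 and 1.5e-15; adjusted p = 0.00341 and 0.0425 with an estimated correlation), and the exact permutation test of the microglia score gave p = 0.0286, the smallest possible. The second call of the pan-macrophage list held without distal_ablated 7 or distal_ablated 9. It was lost without distal_control 1, distal_control 3, distal_control 5, distal_ablated 11 or distal_ablated 13 (adjusted p = 0.0570, 0.0982, 0.0890, 0.137 and 0.0749 with an estimated correlation). Tmem119 ranged from 4215 to 24793 in the 3 non-ablated libraries and from 1169 to 26069 in the 4 ablated ones (adjusted p = 0.772). Sall1 had -0.24 ± 0.37 (adjusted p = 0.905).

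Cell cycle genes were higher in ablated distal tissue. Of 16 members, 14 were positive, with a median of 0.89. By limma 0 rose over all genes, with Ccnb2, a mitotic cyclin, at 16.0 ± 9.54 (SD, n = 3) and 365 ± 460 (SD, n = 4; adjusted p = 0.0575). The mitotic kinase gene Aurkb was at 5.87 ± 7.05 (SD, n = 3) and 45.1 ± 38.1 (SD, n = 4; adjusted p = 0.121). These 2 rose adjusted over the list alone. The list passed camera (adjusted p = 9.4e-06; adjusted p = 0.0330 with an estimated correlation). That second call held without distal_control 5 or distal_ablated 7, and was lost without distal_control 1, distal_control 3, distal_ablated 9, distal_ablated 11 or distal_ablated 13 (adjusted p = 0.0693, 0.0982, 0.0789, 0.0724 and 0.0749 with an estimated correlation). The border macrophage list, macrophages of meninges and vessels, was also higher, with 11 of 12 genes positive, a median of 1.31, 0 rising over all genes and 2 rising adjusted over the list alone. Lyve1 was at 84.4 ± 121 (SD, n = 3) and 311 ± 97.9 (SD, n = 4), and Ms4a7 at 8.18 ± 4.89 (SD, n = 3) and 72.8 ± 64.4 (SD, n = 4; adjusted p = 0.255 and 0.209). Camera called it (adjusted p = 0.00064), but not otherwise (adjusted p = 0.365 with an estimated correlation), and without distal_control 1 its median was 0.34 and its camera adjusted p 0.2495. The median was 0.80 with a pseudocount of 10 and 2.17 with array weights.

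All 19 interferon response genes were negative in ablated distal tissue (median -1.52), 0 fell over all genes and 4 fell adjusted over the list alone. Mx1 lay between 93.8 and 4642 in the non-ablated libraries and between 1.67 and 383 in the ablated ones (adjusted p = 0.195), and Trim30a had -1.11 ± 0.36 (adjusted p = 0.299). The list passed camera (adjusted p = 3.4e-10) but not otherwise (adjusted p = 0.354 with an estimated correlation), and the exact permutation p of its score was 0.2. Its median was -0.87 without distal_control 5, one of the libraries with high T and NK cell scores. Without distal_control 1 it was -2.77 and the call held otherwise as well (adjusted p = 0.0353 with an estimated correlation).

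Complement genes C1qa and C1qb, subunits of the complement starter C1q, fell by 1.62 ± 0.29 and 1.42 ± 0.25, the cytokine gene Osm fell from 45.7 ± 12.9 (SD, n = 3) to 4.42 ± 4.00 (SD, n = 4; adjusted p = 0.0369), and Cst7 fell by 3.02 ± 0.57. Other named genes that fell were the co-stimulatory gene Cd86, from 387 ± 134 (SD, n = 3) to 22.7 ± 23.6 (SD, n = 4), and, to means of a few reads in ablated tissue, Fcrl1 (303 to 2.81), Cd79b (83.8 to 4.92), Siglecf (72.5 to 1.87), Slamf6 (48.8 to 0.593) and Slamf8 (136 to 7.40). Fcrl1 (Entrez 229499; chromosome 3, 87376353 to 87403967) and Cd79b are best known from B cells. Of the 3 measured B cell genes, Cd79b alone fell over all genes, and adjusted over the list alone 1 fell and 1 rose. The 6 genes that rose were Kif22, Myef2 (3.62 ± 0.46; Entrez 17876; chromosome 2, 125080975 to 125123660), Sh3bgrl2 (2.57 ± 0.43), Tshr (4.07 to 55.6), Slc16a13 (3.10 to 86.9) and Mterf2 (0 reads in each non-ablated library, 18.9 ± 24.2, SD, n = 4, in ablated ones).

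Limma called 57 genes, 6 higher and 51 lower, with 1515 at an unadjusted p under 0.05. Camera called 9 of 23 lists, 4 higher and 5 lower, 3 of them with an estimated correlation. The complement list (2 of 11 fell; 3 adjusted over the list alone), the chemokine and cytokine list (1 of 22 fell; 2 adjusted over the list alone) and the myelin and cholesterol biosynthesis lists (0 genes past the threshold) had medians of -0.78, -0.68, 0.23 and 0.29. All 4 were lost otherwise (adjusted p = 0.354, 0.354, 0.609 and 0.385 with an estimated correlation). Camera calls were also lost without distal_control 5 for the complement and chemokine lists (medians -0.064 and -0.12; adjusted p = 0.189 and 0.1302), without distal_control 3 or distal_ablated 7 for the chemokine list (adjusted p = 0.0811 and 0.0504), and without distal_ablated 9 for the myelin list (median 0.12, adjusted p = 0.271). Without distal_control 1 the complement and chemokine medians were -1.44 and -1.34 and the chemokine list passed otherwise too (adjusted p = 0.0314 with an estimated correlation), and without distal_ablated 11 the myelin median was 0.37. The complement and chemokine medians were -0.47 and -0.22 with array weights, -1.24 and -1.12 with edgeR, and -1.21 and -1.08 with DESeq2, and the myelin median was 0.14 after quantile normalization and 0.15 with array weights. Mbp (0.09 ± 0.24, adjusted p = 0.952), Gfap (0.02 ± 0.24, adjusted p = 0.992), Hbegf (0.49 ± 0.25, adjusted p = 0.572) and Arg1 (3.63 ± 0.83, adjusted p = 0.0932) did not pass, and Ccr2 was at 285 ± 400 (SD, n = 3) and 112 ± 76.7 (SD, n = 4; adjusted p = 0.972). The 14 other lists tested, the infiltrating monocyte, T and NK cell and fibroblast lists among them, did not pass (adjusted p from 0.0514 to 0.789). The reactive astrocyte list (median 0.02, mean -0.03) and the lipid efflux and storage list (median -0.11, mean 0.01) differ in sign by median and mean, and the ependymal list has a negative median (-0.24) beside a positive test. The gene count was 11 without distal_control 3, 145 without distal_control 1, 99 without distal_ablated 9, 532 with DESeq2 (34.4% higher, against 10.5% by limma), 63 with edgeR and 0 with these groups fitted alone by limma, so that 0 of the 22 named genes called passed under every setting tried. With the age label as a linear term it was 7, of which limma without that term called 6, Csf3r, Selplg, Kif22 and Cd79b among them. Cx3cr1 then had -4.32 ± 0.80 (adjusted p = 0.0516) and Csf1r -2.86 ± 0.61 (adjusted p = 0.0956), and Slc16a13 had 6.46 ± 1.05 (adjusted p = 0.0516), against 4.25 without the term. The microglia list, with a median of -2.86, passed camera both ways (adjusted p = 1.9e-07; adjusted p = 0.0277 with an estimated correlation), while the pan-macrophage and cell cycle lists (medians -2.22 and 0.95) did not pass otherwise (adjusted p = 0.132 and 0.192 with an estimated correlation). In that fit the border macrophage median was -0.043 and its call was lost (camera adjusted p = 0.879), and camera called 6 more lists, the T and NK cell, infiltrating monocyte, fibroblast, neutrophil and phagocyte lists lower and the progenitor list higher (adjusted p from 0.000167 to 0.0423). Medians were -2.75 for interferon response, -1.48 for chemokine and cytokine, -1.43 for complement, 0.66 for myelin and 0.63 for cholesterol biosynthesis genes. Called genes of the lesion and distal ablation comparisons shared 7 lower genes: Cx3cr1, Csf1r, Cst7, Fcgr1, Capn3, Mef2c and Tal1. The 2 comparisons use pieces of the same pools, so their values are not independent even without an effect. With pieces paired by consecutive title numbers, which the labels do not state, every other of the 35 splits of the pools shared 0 called genes. Other splits of the lesion libraries call 0 genes by themselves, so that shared count was all but fixed and is no measure for the 7. Fold changes correlated across genes with Pearson r = 0.20 (Spearman 0.14), within the -0.061 to 0.25 of those other splits. Genes are not independent replicates.

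In non-ablated mice, lesion and distal tissue show what LPC demyelination changes with microglia present. Gpnmb, a glycoprotein of lipid-laden phagocytes (Entrez 93695; chromosome 6, 49036518 to 49058182), rose by 7.13 ± 0.46, from 712 ± 215 (SD, n = 3) to 98235 ± 18953 (SD, n = 3; adjusted p = 8.3e-07). Mbp (Entrez 17196; chromosome 18, 82475091 to 82585637) fell by 3.33 ± 0.26, from 1281660 ± 175796 (SD, n = 3) to 129367 ± 30228 (SD, n = 3; adjusted p = 1.4e-06). Gfap (Entrez 14580; chromosome 11, 102887336 to 102897200) fell by 2.39 ± 0.25 and Vim, the intermediate filament of reactive glia and many other cells, rose by 1.94 ± 0.28. Cx3cr1 rose by 2.27 ± 0.54 and Csf1r by 1.56 ± 0.40.

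All 16 myelin genes fell (16 adjusted over the list alone), with a median of -3.00, among them Mobp (-3.75 ± 0.22), Mog (-3.52 ± 0.27) and Ermn (-3.05 ± 0.25). All 12 astrocyte genes fell (12 adjusted over the list alone; median -2.63), among them Aldoc (-3.47 ± 0.31), Mlc1 (-3.41 ± 0.30) and the gap junction gene Gja1 (-3.00 ± 0.28). Of 16 cholesterol biosynthesis genes, 14 fell (15 adjusted over the list alone; median -2.14), including the synthetic enzyme gene Hmgcs1 (-2.26 ± 0.22). Of 12 lipid efflux and storage genes, 8 rose (10 adjusted over the list alone; median 2.56), including the cholesterol exporter gene Abca1 (3.26 ± 0.25) and the lipid droplet gene Plin2 (4.15 ± 0.41). Of 17 disease-associated phagocyte genes, 16 rose (17 adjusted over the list alone; median 3.67), including Spp1 (7.27 ± 0.73) and Igf1 (6.17 ± 0.41). Of 16 cell cycle genes, 15 rose (15 adjusted over the list alone; median 4.65), including Top2a (4.25 ± 0.51) and Aurkb (7.01 ± 0.76). These 6 lists passed camera and kept the call with an estimated correlation (adjusted p = 0.0487, 0.0418, 0.0418, 0.0487, 0.0418 and 0.00749). With single libraries left out, the cell cycle list alone held that second call throughout. The phagocyte list lost it without distal_control 1 or distal_control 5, the astrocyte and cholesterol biosynthesis lists without distal_control 1, distal_control 3 or distal_control 5, and the myelin and lipid lists without any of those or lesion_control 6 (adjusted p from 0.0538 to 0.0675 with an estimated correlation).

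Of 16 pan-macrophage genes, 13 rose (15 adjusted over the list alone), including Cd68 (5.10 ± 0.55) and Mpeg1 (4.64 ± 0.38), and of 14 fibroblast and extracellular matrix genes, 13 rose and 1 fell (the same counts adjusted over the list alone), including Col1a1 (6.56 ± 0.72) and Col3a1 (6.06 ± 0.71). Of 11 complement genes, 7 rose and 1 fell (7 and 1 adjusted over the list alone), including C3ar1 (5.03 ± 0.33) and C1qb (2.81 ± 0.26). Camera called these 3 lists higher (adjusted p = 9.2e-10, 3.8e-07 and 0.000479), but not otherwise (adjusted p = 0.0776, 0.0934 and 0.157 with an estimated correlation). Of 13 homeostatic microglia genes, 4 rose (5 adjusted over the list alone) and 9 were positive, with Fcrls at 3.63 ± 0.41 (camera adjusted p = 0.0462; adjusted p = 0.195 with an estimated correlation). The camera call of that list was lost without distal_control 1, lesion_control 2, distal_control 5 or lesion_control 6 (adjusted p = 0.0932, 0.0602, 0.119 and 0.0566). Over the border macrophage, infiltrating monocyte, chemokine and cytokine, and neutrophil lists, 6 of 12, 7 of 16, 5 of 22 and 3 of 8 genes rose (6, 8, 4 and 3 adjusted over the list alone, where 1 infiltrating monocyte gene also fell), such as Ms4a7 (7.15 ± 0.79), Arg1 (8.59 ± 0.88) and Ccl3 (3.97 ± 0.75). Mmp8 rose from 0.424 ± 0.734 (SD, n = 3) to 244 ± 56.9 (SD, n = 3). Camera called these 4 higher and none otherwise (adjusted p = 0.195, 0.33, 0.176 and 0.192 with an estimated correlation). Without distal_control 1 the neutrophil call was lost (camera adjusted p = 0.0999) and the chemokine and cytokine median was 1.07, against 2.08 with all libraries, 1.09 with a pseudocount of 10, 1.19 with edgeR and 1.23 with DESeq2.

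In the interferon response list 18 of 19 genes were positive and 2 rose (1 adjusted over the list alone), Trim30a by 1.89 ± 0.39, while Irf7 did not pass (2.89 ± 1.07, adjusted p = 0.0568). Its camera call (adjusted p = 0.0133) was lost otherwise (adjusted p = 0.567 with an estimated correlation). The median of 1.5 was 0.30 without distal_control 1, where camera did not call the list (adjusted p = 0.599), 2.54 without distal_control 5, 0.49 with edgeR and 0.53 with DESeq2. Neuron, endothelial and pericyte, and ependymal lists were called lower, with 2 of 16, 6 of 14 and 3 of 7 genes falling (0, 6 and 3 adjusted over the list alone). They had medians of -1.36, -0.94 and -1.94 and were lost otherwise (adjusted p = 0.567, 0.192 and 0.133 with an estimated correlation). The neuron call was lost without distal_control 1, distal_control 3 or lesion_control 6 (medians -0.58, -1.26 and -0.88; camera adjusted p = 0.2697, 0.0611 and 0.118), and its median was -2.24 without distal_control 5. The ependymal call was lost without lesion_control 4 or distal_control 5 (camera adjusted p = 0.0642 and 0.0910), and its median was -1.28 without distal_control 3, -0.999 with a pseudocount of 10 and -1.03 with a filter at 50. The oligodendrocyte progenitor list went both ways, with Cspg4 rising by 2.68 ± 0.38 and Olig1 falling by 1.44 ± 0.28, and did not pass (camera adjusted p = 0.969). The reactive astrocyte, Schwann cell, T and NK cell and immediate early gene lists did not pass either (adjusted p = 0.786, 0.64, 0.422 and 0.15). Among lists not tested, 1 of 3 B cell genes, 1 of 3 MHC class II genes and 0 of 3 blood cell genes rose.

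The largest rises among named genes were Cd5l, a macrophage scavenger protein (10.44 ± 1.63; Entrez 11801; chromosome 3, 87357881 to 87371074), Arg1, Acp5 (2.97 to 1627), and, from under 2 normalized counts on average in distal tissue, Atp6v0d2 (933 ± 165, SD, n = 3, in lesions), Fabp4 (1047 ± 113, SD, n = 3) and Prss46 (924 ± 16.0, SD, n = 3). The largest falls were Dao, D-amino acid oxidase (-6.66 ± 0.59; Entrez 13142; chromosome 5, 113999635 to 114025675), Fn3k (-4.98 ± 0.61), Ucma (-4.91 ± 0.48) and, to a few reads in lesions, Opn4 (110 to 1.35), Gipr (165 to 3.20) and Il25 (184 to 5.47). Limma called 4374 genes, 2298 higher and 2076 lower. Camera called 18 of 23 lists, 12 higher and 6 lower, 6 of them with an estimated correlation. Of the 18, fry, which tests whether a list's genes move one way and does not compare them with other genes, also called 16, all but the interferon response and neuron lists. With the age label as a linear term the camera call of the microglia list was lost (adjusted p = 0.0538), and the myelin and lipid lists did not pass otherwise (adjusted p = 0.0507 with an estimated correlation for each). Tmem119 (1.68 ± 0.89, adjusted p = 0.187), Sall1 (-0.48 ± 0.39, adjusted p = 0.406), Hbegf (0.08 ± 0.27, adjusted p = 0.871) and Ccr2 (2.83 ± 1.23, adjusted p = 0.106) did not pass.

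The lesion response in ablated mice shows what LPC demyelination changes after ablation. Gpnmb rose by 7.11 ± 0.40, from 2003 ± 1431 (SD, n = 4) to 234056 ± 55327 (SD, n = 4; adjusted p = 7.2e-08), and Mbp fell by 2.85 ± 0.23, from 1365100 ± 190811 (SD, n = 4) to 188828 ± 20972 (SD, n = 4; adjusted p = 7.6e-07). Gfap fell by 1.66 ± 0.22 and Vim rose by 2.14 ± 0.24. Cx3cr1 rose by 1.74 ± 0.47, between low group means of 80.2 ± 43.9 (SD, n = 4) and 236 ± 75.7 (SD, n = 4), while Sall1 fell by 1.88 ± 0.34.

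All 16 myelin genes fell (16 adjusted over the list alone; median -2.63), including Mobp (-3.22 ± 0.19) and Mog (-2.94 ± 0.23). Further, 11 of 12 astrocyte genes fell (11 adjusted over the list alone), including Mlc1 (-2.45 ± 0.26) and Slc1a3 (-2.05 ± 0.19), and 15 of 16 cholesterol biosynthesis genes fell (16 adjusted over the list alone; median -2.08), including Msmo1 (-2.30 ± 0.18). Of 16 pan-macrophage genes, 15 rose (16 adjusted over the list alone; median 4.06), including Mpeg1 (5.11 ± 0.33) and Cd53 (5.78 ± 0.38). Of 17 disease-associated phagocyte genes, 15 rose (16 adjusted over the list alone; median 3.69), including the lipoprotein lipase gene Lpl (4.20 ± 0.31). Of 12 lipid efflux and storage genes, 9 rose (9 adjusted over the list alone; median 2.67), including Abca1 (3.42 ± 0.22). Of 16 cell cycle genes, 13 rose (14 adjusted over the list alone; median 2.71), including Top2a (2.49 ± 0.45) and Bub1 (2.96 ± 0.51). All 7 lists passed camera and kept the call (adjusted p = 0.0469 for myelin and 0.0346 for each of the others with an estimated correlation). Each of them lost that second call without lesion_ablated 8, distal_ablated 9 or distal_ablated 13 (adjusted p from 0.0505 to 0.0660 with an estimated correlation), and the myelin list also without distal_ablated 7 or lesion_ablated 10 (adjusted p = 0.0666 and 0.0581 with an estimated correlation).

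Of 13 homeostatic microglia genes, 5 rose and 3 fell (5 and 3 adjusted over the list alone), Fcrls by 2.06 ± 0.35, Selplg by 2.55 ± 0.31 and Csf1r by 2.14 ± 0.35 upward. The list did not pass (adjusted p = 0.333), and its median of 0.99 was -0.07 with edgeR or DESeq2. Fibroblast and matrix genes rose in 12 of 14 cases and fell in 1 (13 and 1 adjusted over the list alone), with Col3a1 at 6.74 ± 0.62, and neutrophil genes rose in 6 of 8 (6 adjusted over the list alone), with Csf3r at 3.94 ± 0.31 and Mmp8 at 6.84 ± 0.85. Of 11 complement genes, 8 rose, C1qb by 3.63 ± 0.23, and 1 fell (8 and 1 adjusted over the list alone). Of 22 chemokine and cytokine genes, 9 rose (9 adjusted over the list alone), Osm by 5.23 ± 0.61. Of 16 infiltrating monocyte genes, 9 rose (10 adjusted over the list alone), Arg1 by 6.72 ± 0.77. Of 12 border macrophage genes, 7 rose (8 rose and 1 fell adjusted over the list alone), and of 10 immediate early genes, 4 rose (4 adjusted over the list alone). Camera called these 7 lists higher. None of the 7 kept the call otherwise (adjusted p = 0.0729, 0.0765, 0.0765, 0.152, 0.3198, 0.244 and 0.244 with an estimated correlation). The immediate early gene call was lost without distal_ablated 7, distal_ablated 9, lesion_ablated 12 or distal_ablated 13 (camera adjusted p = 0.0599, 0.0582, 0.0574 and 0.0827). Without distal_ablated 11 its median was 1.14, against 0.585 with all libraries, and it passed otherwise too (adjusted p = 0.0475 with an estimated correlation). The interferon response list did not pass (median 0.51, adjusted p = 0.451), nor did the T and NK cell, oligodendrocyte progenitor, reactive astrocyte, neuron, endothelial and pericyte, Schwann cell and ependymal lists (adjusted p = 0.285, 0.611, 0.285, 0.318, 0.318, 0.732 and 0.0774). Among lists not tested, 2 of 3 B cell genes rose and 1 fell, 1 of 3 MHC class II genes rose (2 adjusted over the list alone), and 0 of 3 blood cell genes passed.

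Named genes with the largest rises were Mmp12, a macrophage elastase (3.21 ± 2.82 to 4138 ± 1704, SD, n = 4), Fcrl1 (2.81 to 1567), F7 (1.34 to 1299), Cd5l (9.24 ± 1.41), Cd22 (5.14 to 1568) and Atp6v0d2 (5.56 to 2563). The largest falls were Dao (-4.86 ± 0.51), Galnt5 (-4.55 ± 0.80), Pdyn (-4.77 ± 1.12) and, to a few reads in lesions, Apela (264 to 2.64), Rnase1 (475 to 4.99) and Banf2, whose distal log2 value was 12.13 in distal_ablated 9 and 5.68 to 6.25 in the other 3 libraries. Limma called 4678 genes, 2520 higher and 2158 lower. Camera called 14 of 23 lists, 11 higher and 3 lower, 7 of them with an estimated correlation, and fry also called all 14. Tmem119 (0.20 ± 0.77, adjusted p = 0.882), Hbegf (-0.04 ± 0.24, adjusted p = 0.921) and Ccr2 (2.63 ± 1.07, adjusted p = 0.0784) did not pass. Fold changes of the lesion response in both genotypes, which share no libraries, correlated across genes with Pearson r = 0.81 (Spearman 0.77). By limma 1710 genes were called higher in both against 370 expected of independent lists, 1591 lower in both against 287, and 3 were called in opposite directions.

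**Figure D2:**
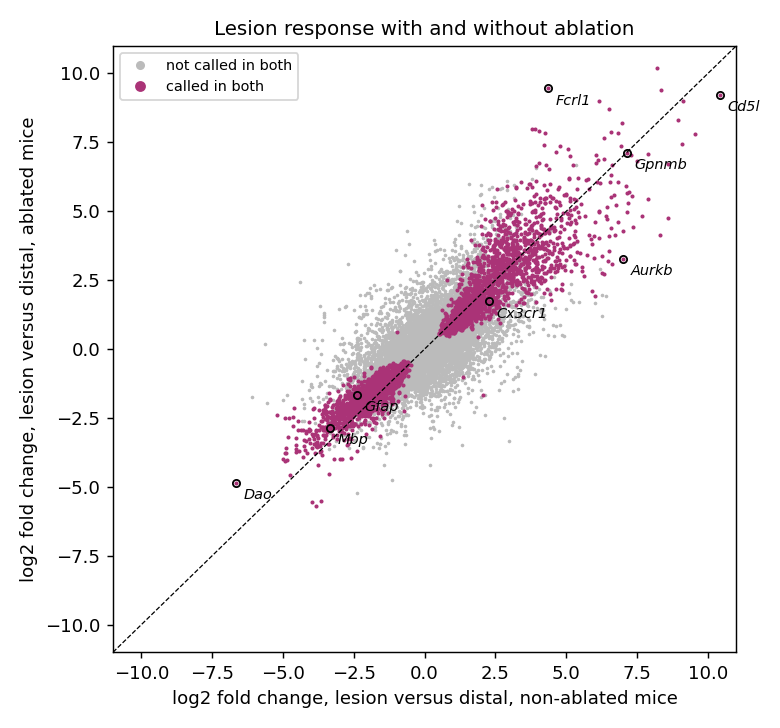
Log2 fold change of lesion against distal tissue for 15637 genes in non-ablated (x axis) and ablated mice (y axis), with genes called in both coloured and equal values on the dashed line. Gpnmb lies at 7.13 and 7.11, and Mbp at -3.33 and -2.85.

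**Figure D3:**
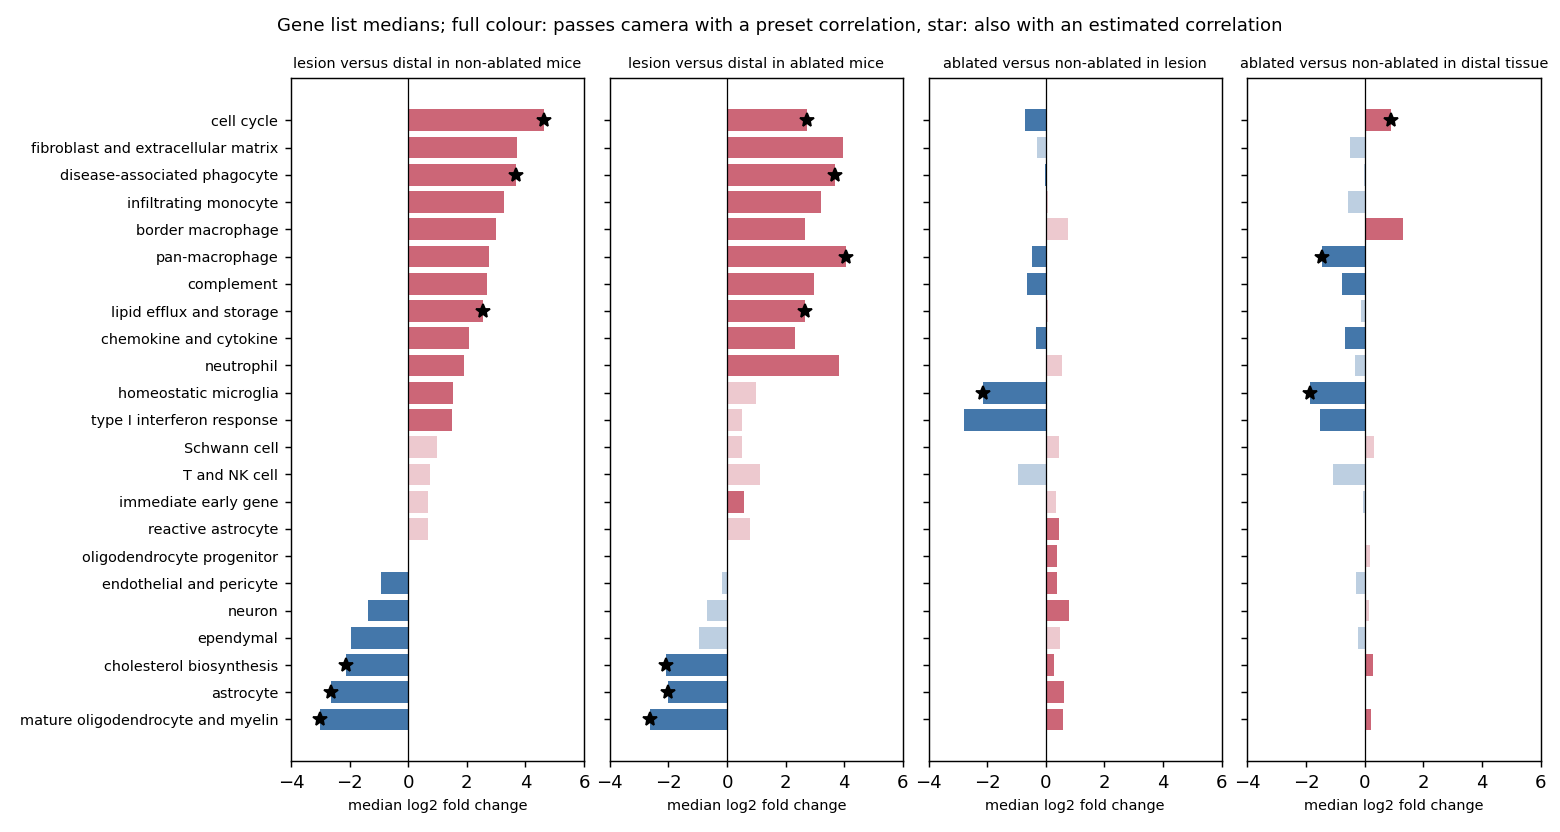
Median log2 fold change of the 23 gene lists tested (bars) in 4 comparisons; full colour marks lists past camera with a preset correlation and stars those also past it with an estimated correlation. Homeostatic microglia genes have medians of -2.15 in lesions and -1.86 in distal tissue with ablation.

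The interaction asks whether the lesion response differed between genotypes. Kif22 differed by -3.66 ± 0.49 on the log2 scale (adjusted p = 0.0383). It was at 81.7 ± 32.5 (SD, n = 3) in distal and 1809 ± 179 (SD, n = 3) in lesion tissue of non-ablated mice, and at 752 ± 204 (SD, n = 4) and 1415 ± 584 (SD, n = 4) in ablated mice. Cdhr3, a cadherin family gene (Entrez 68764; chromosome 12, 33033795 to 33092901), differed by -4.80 ± 0.68 (adjusted p = 0.0383), at 10.0 ± 0.136 (SD, n = 3) and 166 ± 27.3 (SD, n = 3) in non-ablated and 43.1 ± 15.0 (SD, n = 4) and 23.3 ± 10.4 (SD, n = 4) in ablated mice. The cell cycle list had a smaller lesion response in ablated mice, with 15 of 16 genes negative and a median of -1.75. Over all genes 0 fell, and 2 did adjusted over the list alone, with Ccnb2 at -4.50 ± 1.11 (adjusted p = 0.518) and Aurkb at -3.73 ± 1.00 (adjusted p = 0.558). It passed camera (adjusted p = 2.0e-09; adjusted p = 0.00794 with an estimated correlation), and did so without each library in turn (adjusted p from 0.00346 to 0.0485 with an estimated correlation).

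Camera called 5 further lists of 23: pan-macrophage (median 0.67; 15 of 16 genes positive, 1 adjusted over the list alone), endothelial and pericyte (0.83), astrocyte (0.52), myelin (0.28) and interferon response (-1.30; 15 of 19 genes negative), none of them otherwise (adjusted p = 0.627, 0.627, 0.743, 0.743 and 0.743 with an estimated correlation). The pan-macrophage list passed camera without each library in turn, with a median of 1.14 without distal_control 1 or distal_ablated 9. The interferon call was lost without distal_control 1 or distal_ablated 11 (medians 0.027 and -0.97; camera adjusted p = 0.867 and 0.0967), with a median of -0.67 by edgeR and -0.68 by DESeq2, and the endothelial and pericyte call without lesion_control 2, distal_control 5 or distal_ablated 11 (medians 0.65, 0.49 and 0.76; camera adjusted p = 0.0603, 0.194 and 0.0545). The myelin call was lost without distal_control 1, lesion_control 4, lesion_control 6, lesion_ablated 10, distal_ablated 11, lesion_ablated 12 or distal_ablated 13 (medians 0.14 to 0.29; camera adjusted p from 0.0624 to 0.402), and its median was 0.52 without lesion_control 2. The astrocyte call was lost without distal_control 3, lesion_control 4, lesion_control 6, distal_ablated 7, lesion_ablated 10, distal_ablated 11, lesion_ablated 12 or distal_ablated 13 (medians 0.30 to 0.59; camera adjusted p from 0.0531 to 0.143). The other 17 lists did not pass (adjusted p from 0.0626 to 0.875). Medians and tests differed in sign for the infiltrating monocyte list (median 0.38, mean 0.22, test lower), the Schwann cell list (0.08, 0.10, lower) and the cholesterol biosynthesis list (0.02, -0.06, lower). Genes that did not pass included Mfge8 (1.71 ± 0.31, adjusted p = 0.183), Epas1 (1.61 ± 0.31, adjusted p = 0.209), Dnal1 (2.58 ± 0.49, adjusted p = 0.209), Csf3r (2.31 ± 0.48, adjusted p = 0.294), and Cspg4 (-1.71 ± 0.50, adjusted p = 0.675). Nor did Cx3cr1 (-0.53 ± 0.72, adjusted p = 0.972), Csf1r (0.57 ± 0.53, adjusted p = 0.96), Mbp (0.48 ± 0.34, adjusted p = 0.939) or Gfap (0.73 ± 0.33, adjusted p = 0.868). Limma called 2 genes, both lower, with 885 at an unadjusted p under 0.05; edgeR also called 2 and DESeq2 94 (57.4% higher). With a replicate block by consecutive title numbers, a pairing that the labels do not state and that was chosen after seeing the data, limma called 0 genes (adjusted p = 0.229 for Kif22 and 0.533 for Cdhr3) and camera 10 lists. With the age label as a linear term, limma called Kif22 alone (adjusted p = 0.0780 for Cdhr3). The count was 2 without distal_control 5 or distal_ablated 11, where Kif22 passed and Cdhr3 did not (adjusted p = 0.0737 and 0.0777). It was 1 without distal_control 3 or lesion_ablated 8, and 0 without any 1 of the other 10 libraries. The list count was 3 without distal_ablated 11.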

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

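Tests chosen only after the result was seen were those that leave out a single pool, the share of unlesioned tissue, the loss of microglial RNA, the scaling of the libraries, lesion tissue within distal pieces, and a steady trend with labelled age. Labelled age was set in the fit as a linear term with 1 slope over the groups. In ablated lesions the interferon score differed between genotypes by -4.10 with the term (interval of 2 SE -6.72 to -1.49), against -2.74 without it. The myelin score differed by 0.96 (0.33 to 1.60), against 0.58 without. Neither difference shrank with the term. Both intervals only just exclude that such a trend accounts for most of the difference, and 2 SE is short for so few libraries. They also count pieces of 1 pool as independent, so the trend cannot be excluded here. It stays open for interferon genes in distal tissue (-3.26, interval -5.88 to -0.65; -1.90 without), astrocyte and neuron genes in lesions (0.79, 0.17 to 1.40; 0.57 without, and 1.196, -2.07 to 4.46; 1.05 without) and cell cycle genes in distal tissue (1.32, 0.47 to 2.17; 1.35 without), where the intervals are too wide to exclude that it accounts for most of the difference. A step in age between the genotypes or a curved trend stays open for each difference with ablation, as untested.

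Single libraries lay far from the other 3 of their group for 13 of 268 groups of values, about the 1 in 20 that chance gives. In distal_ablated 9, log2 values were 0 for Opn4 (others 6.09 to 7.13), 7.92 for Csf1r (9.66 to 9.92), 12.13 for Banf2 (5.68 to 6.25), 11.09 for Olfml3 (9.10 to 9.38), 12.63 for Mgst1 (11.51 to 11.57) and 5.81 for Mterf2 (2.79 to 3.05). Capn3 was at 3.22 in distal_ablated 7 (others 5.19 to 5.47), Slamf6 at 1.75 in distal_ablated 7 and Cd79b at 4.37 in distal_ablated 13, where the other 3 libraries were at 0. In lesion_ablated 14, Mfge8 was at 14.24 (others 13.88 to 13.91). Pdyn was at 0 in lesion_ablated 8 (others 3.84 to 4.57) and Lrrc3 at 3.17 in lesion_ablated 10 (4.77 to 4.95). The library lesion_ablated 8 had 16933 genes detected against 17696 to 17839 in the others of its group.

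The test of the interaction, which ignores that lesion and distal pieces come from the same pools, called Kif22 (-3.66), Cdhr3 (-4.80) and 6 lists. With the replicate block by consecutive title numbers, chosen after seeing the data, it called 0 genes and 10 lists. The list medians were 0.67 for pan-macrophage, -1.30 for interferon response, 0.28 for myelin, 0.52 for astrocyte, 0.83 for endothelial and pericyte, and -1.75 for cell cycle genes. Of these lists, the cell cycle list alone also passed with an estimated correlation. Calls of the interferon, myelin, astrocyte and endothelial and pericyte lists were lost without single libraries.

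Camera at a preset correlation called the interferon response list lower with ablation in both regions, but neither call held otherwise. In distal tissue 0 genes fell over all genes and the exact permutation p of the score was 0.2. In lesions the tables argue against a single non-ablated pool as the cause, since the median was -2.88 without lesion_control 6 (-2.78 with all libraries, -2.92 to -2.61 over each library left out), and against the sex makeup of the pools, since it was -2.75 with a Y-linked score in the fit. In distal tissue a single pool stays open, because the median was -0.87 without distal_control 5, -2.77 without distal_control 1 and -1.52 with all libraries. Loss of the Cx3cr1-expressing cells themselves, the design's own explanation, may account for the fall and also stays open: the interferon score fell by as much as the microglia score within the spread (difference -0.12, interval -0.65 to 0.42). Whether other cells made less interferon-induced RNA was not tested.

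Camera at a preset correlation called oligodendrocyte, astrocyte and neuron lists higher in ablated lesions. No single gene passed the threshold over all genes and no call held otherwise. The neuron call was lost without lesion_ablated 10 (median 0.49, 0.80 with all libraries), and without lesion_ablated 14 the astrocyte list passed otherwise. A larger share of unlesioned tissue is a candidate explanation for the myelin and astrocyte genes. They give median shares of 6.61% (1.62 to 8.69 over the 4 libraries) and 11.0% (-1.03 to 16.0), a gap of 4.37 points with overlapping ranges. Non-ablated lesions gave -2.95 to 4.98 and -3.48 to 2.60, set against their own mean and non-ablated distal tissue. Those values centre near 0 by construction and show only the spread. The neuron genes, at 23.0% (-7.84 to 110.4), are too spread to decide on this explanation for their list. Loss of microglial RNA, which would raise all other transcripts alike, could not be decided, as the fibroblast and matrix score minus the myelin score changed by -0.84 (interval -1.80 to 0.11; exact two-sided permutation p = 0.143). A biological difference in myelin loss or debris between the genotypes stays open and was not tested.

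The cell cycle list was higher in ablated distal tissue, with 0 single genes past the threshold over all genes. The tables argue against a single ablated pool as the source of its median, which was 1.02 without distal_ablated 9 (0.89 with all libraries, 0.64 to 1.24 over each library left out). Against lesion tissue in the distal pieces, the fibroblast and matrix median was -0.51, and that score reached at most 7.81 where a lesion share of 13.4%, which the cell cycle genes would need, gives 9.53. Against the scaling of the libraries, which would move genes of like level alike, those genes had a median of -0.015, and the cell cycle genes exceeded them by a median of 0.87 (0.73 to 1.31 over each library left out). Chance, age and ablation itself stay open. The call with an estimated correlation was lost without distal_control 1, distal_control 3, distal_ablated 9, distal_ablated 11 or distal_ablated 13. It was also lost with the age label in the fit, and other splits of the libraries call as many lists.

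Real groupings were set against other splits of the same libraries. For genes, the count for ablation in lesions was above that of every other split (46, highest other 0). That share, 1 of 35 splits, is the smallest possible and was not adjusted for the other comparisons. It makes chance unlikely there but does not exclude it. In the lesion response of ablated mice 1 of 35 splits was as large too (4678 genes, highest other 1), but these splits exchange pieces between pools. Swaps within pools, paired by consecutive title numbers, make only 8 splits, too few for a share under 0.05 (highest other 0). It could not be excluded for ablation in distal tissue (57, highest other 157; 2 of 35) or the interaction (2, highest other 7; 5 of 100 splits drawn from 1225, without regard to which pieces share a pool). The distal split that called 157 genes set distal_control 1, distal_control 3, distal_ablated 11 and distal_ablated 13 against the other 3 libraries, so the distal samples may hold a structure that the groups leave out. The split was picked for its count, and no such structure was tested. For the lesion response in non-ablated mice the 10 splits are too few for a share under 0.05 (4374 genes, highest other 0; 1 split as large). For lists the 10 splits are too few there as well (18, highest other 18; 2 as large). For the other 4 comparisons the count of lists could not be told from chance. It was 14 against a highest other of 16 in the ablated lesion response (8 of 35), whose splits again exchange pieces between pools. For ablation it was 14 against 15 in lesions (5 of 35) and 9 against 14 in distal tissue (14 of 35). For the interaction it was 6 against 17 (60 of 100), again without regard to shared pools.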

How the results depend on the processing

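Alternatives chosen after seeing the data were the Y-linked score, the age label, the replicate block by consecutive title numbers, and leaving out distal_control 5 with lesion_control 6. Gene counts of both lesion responses stayed within 1.5 times under every setting. Of named genes called, 41 of 44 (non-ablated lesion response), 37 of 38 (ablated lesion response), 2 of 20 (ablation in lesions), 0 of 22 (ablation in distal tissue) and 0 of 2 (interaction) passed under every setting. Named genes gave 3691 values on the same side, 301 no longer past the threshold, 93 newly past it and 32 of opposite sign. Where counts fell without a library, fewer samples were tested, and with the age label standard errors of both ablation comparisons were 1.61 times as large at the median. For all other changes the cause was not tested.

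For ablation in lesions (46 genes, 10.9% higher), the count was 101 after quantile normalization, 98 with a pseudocount of 10, 1013 with array weights (45.4% higher), 259 with DESeq2 (34.4% higher), 416 with only the groups compared (25% higher), 30 with the Y-linked score, 2 with the age label and 9 without distal_control 5 and lesion_control 6. The microglia median was -2.51 after quantile normalization, -2.99 with the age label and -2.37 without those 2 libraries. For ablation in distal tissue (57 genes, 10.5% higher), the count was 532 with DESeq2 (34.4% higher), 0 with only the groups compared by limma, 7 with the age label (and 14 lists, against 9) and 20 without those 2 libraries, and the microglia median was -1.25 with edgeR, -1.19 with DESeq2 and -2.86 with the age label. For the interaction (2 genes), the count was 0 without a filter, 1 with a filter at 50, 6 with array weights, 94 with DESeq2 (57.4% higher), 0 without those 2 libraries, 0 with the Y-linked score and 1 with the age label. Lists called with an estimated correlation numbered 6 in the non-ablated and 7 in the ablated lesion response, 1 for ablation in lesions, 3 in distal tissue and 1 for the interaction, and fry, which does not compare a list with other genes, called 17, 16, 1, 3 and 1. Of camera's 18, 14, 14, 9 and 6 lists, fry also called 16, 14, 1, 3 and 1.

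Leaving out each library gave 3053 to 4008 genes and 14 to 17 lists in the non-ablated lesion response, 3653 to 4748 and 13 to 14 in the ablated one, 5 to 36 and 11 to 16 for ablation in lesions (microglia median -2.37 to -2.11), 11 to 145 and 8 to 13 in distal tissue (-2.67 to -1.69), and 0 to 2 and 3 to 9 for the interaction. In lesions the count was 5, 8 and 9 without lesion_control 2, 4 and 6, and 16, 14 and 11 without lesion_ablated 8, 10 and 12. In distal tissue it was 145 and 11 without distal_control 1 and 3, and 99 without distal_ablated 9. The interaction count was 2 only without distal_control 5 or distal_ablated 11, where Kif22 passed and Cdhr3 did not.

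Genes of opposite sign were never called. In distal tissue with ablation, Gfap was -0.0095 after TMM, -0.028 after quantile normalization and -0.023 with edgeR (in brackets, here and for the genes that follow, the range over libraries left out singly: -0.15 to 0.13). Ccr2 was -0.052 with a pseudocount of 10, -1.35 with edgeR, -1.34 with DESeq2 and -1.55 with the age label (-1.57 to 1.91), Sall1 0.062 with the age label (-0.73 to 0.021), and Tmem119 0.77 with the age label. In lesions with ablation, Ccr2 was -0.13 with edgeR, -0.11 with DESeq2 and -1.75 with the age label (-0.52 to 0.60). In the ablated lesion response, Tmem119 was -0.57 with edgeR and -0.55 with DESeq2 (-0.44 to 1.05) and Hbegf 0.090 after quantile normalization, 0.0059 with DESeq2 and 0.040 with the age label (-0.27 to 0.061). In the non-ablated one, Hbegf ranged from -0.12 to 0.22 over libraries left out singly, and was 0.25 without distal_control 5 and lesion_control 6.

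The median log2 fold change of all genes moved by over 0.1 in the lesion responses with quantile normalization and with edgeR and DESeq2, which change the model too: from 0.072 to -0.030, -0.074 and -0.032 in non-ablated mice, and from 0.047 to -0.094, -0.089 and -0.073 in ablated mice. With TMM and upper-quartile scaling it was 0.033 and 0.082, and 0.032 and 0.067. Medians that changed sign with a scaling or count test were those of homeostatic microglia and Schwann cell (ablated lesion response), oligodendrocyte progenitor (non-ablated lesion response), infiltrating monocyte and lipid efflux (ablation in lesions), disease-associated phagocyte, astrocyte, reactive astrocyte and ependymal lists (ablation in distal tissue), and T and NK cell, Schwann cell and cholesterol biosynthesis lists (interaction).

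The labels do not tie the lesion to the distal piece of a pool, so no pairing could be taken from them. The replicate block by consecutive title numbers, at which Y-linked genes hint, gave 4086 genes and 18 lists in the non-ablated and 4455 and 14 in the ablated lesion response, and 0 genes and 10 lists for the interaction.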

Other observations

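The test of pairing by Y-linked genes was chosen only after the result was seen. Genes named here outside the naming rule were chosen after their values were seen.

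Besides the list members, single genes were called lower in ablated lesions. Gas6, a ligand of the Axl and Mertk receptors, fell by 1.43 ± 0.16 on the log2 scale (limma adjusted p = 0.00301) and the transcription factor gene Mef2c by 1.81 ± 0.24 (adjusted p = 0.00538). Sall3, a relative of Sall1, had a log2 fold change of -3.24 ± 0.43 (adjusted p = 0.00566) and the niacin receptor gene Hcar2 of -4.18 ± 0.74 (adjusted p = 0.0306). Ly6e, an interferon-induced gene outside the list, fell by 1.84 ± 0.36 (adjusted p = 0.0496).

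Further single genes were called lower in ablated distal tissue. Irf8 had a log2 fold change of -1.68 ± 0.28, Runx1 of -2.47 ± 0.41 and Lmo2 of -1.61 ± 0.30 (adjusted p = 0.0237, 0.0237 and 0.0369). Tgfbr1, a receptor for TGF-beta, had -1.93 ± 0.25 (adjusted p = 0.00483), and the signalling genes Csf2rb, Vav1, Ptpn6 and Blnk had -2.76, -1.93, -1.87 and -2.18. Mef2c and Tal1 were called lower in both regions. Chance stays open for the distal calls, as another split of the libraries called 157 genes against 57. Of 22 named distal calls, 0 passed under every setting.

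Among list genes, 19 were at 0 reads in every library, P2ry12 included. A hypothesis is that reads in overlapping gene spans were left out of the counts: 63.2% of these genes (12 of 19) overlap the span of another gene of the table against 15.6% (49 of 315) of tested list genes (Fisher's exact p = 9.2e-06). Examples are P2ry12 and P2ry13 within Med12l, Gpr34 with Cask, Cxcl10 with Art3, Timp1 with Syn1 and Gpr17 with Lims2. A 0 for such a gene may thus reflect the counting, and the 7 genes at 0 without an overlap, 6 of them MHC class II genes, stay unexplained.

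Y-linked scores hint that consecutive title numbers mark lesion and distal pieces of 1 pool. The sum of absolute score differences over the 7 consecutive pairs was 3.39, against a median of 13.8 over all 144 pairings within genotype, and 2 of the 144 were as small. Scores were, for example, 3.67 in distal_control 3 and 3.56 in lesion_control 4, and 7.72 in distal_control 5 and 8.32 in lesion_control 6. The labels do not state this pairing, so it may be considered only as a hypothesis.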
